A study of Mus musculus with 90 samples.

How the data were processed

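Whole lungs of 90 male mice were profiled on Affymetrix HT MG-430 PM arrays, 1 array per animal. The animals form 18 groups of 5, given by 3 strains, exposure for 1 or 4 weeks, and 0, 40 or 120 ppm inhaled styrene. Group and replicate number were taken from the sample labels. RNA was extracted with Trizol and RNeasy columns and labelled with a 3' IVT kit, per the labels' protocols.

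The deposited values are log2 expression values per probe set. RMA and Partek are named in the submitters' processing notes, and their versions are not given in the sources used here. The table holds 45141 probe sets and 90 columns, each matched to a sample by its label, with 0 missing values. The 104 control probe sets were left out of the gene tests. The platform annotation lists 29449 probe sets, 28898 with 1 gene symbol and 551 with several, and 15588 other probe sets have no listed gene. Probe sets with several or no listed genes were not named. Of the genes tested, 16936 matched a RefSeq gene of assembly GRCm38.p6 through the Entrez identifier, and 0 of their symbols differed. That assembly was used only for names and for which genes neighbour each other. Expression of the human transgenes was not checked here.

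Each gene was represented by its probe set with the highest mean over the 90 arrays, which gave 17097 genes, 7180 of them with several probe sets. A linear model with 18 group means was fitted to the log2 values of all 90 arrays with limma, giving 72 residual degrees of freedom, and its empirical Bayes test was used. P-values were adjusted by the Benjamini-Hochberg method over the 17097 genes, and an adjusted p under 0.05 passed. There were 24 comparisons. They were the 3 differences between unexposed strains (10 animals per strain, both times averaged), 12 differences between an exposed group and its control, 6 differences between strains in the 120 ppm change, the difference between 120 and 40 ppm in wild-type mice at each time, and the difference between times in the wild-type 120 ppm change. The design assumed that replicate numbers do not pair animals. Differences between strains in the 40 ppm change were not tested across genes.

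The lists of genes were 36 sets of lung cell type markers, markers of other tissues, metabolic and stress processes, and loci. Each was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 36 lists within a comparison. The p given for a list is that of camera with an estimated correlation unless stated otherwise. Cyp2f2 in unexposed strains was also tested with a two-sided permutation test of 100000 resamples.

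Named genes followed a rule. It takes up to 12 genes with the largest rise and up to 12 with the largest fall among those that passed for the strain and 120 ppm comparisons, and up to 5 and 5 for the others. Where fewer than 3 passed, it takes the 3 with the smallest p. It takes up to 4 members of each list described, by size among those that passed, or among all members where none did. Cyp2f2, Scgb1a1, Scgb3a2, Mki67, Fkbp5, Dbp and Per1 could be given in any comparison. Predicted genes without a standard symbol were named only among the first 5 by size.

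Alternatives were quantile normalization applied again, dim genes left out (mean below the 40th percentile), the median over a gene's probe sets, a fit of only the arrays compared, an intensity trend with robust hyperparameters, array weights, the replicate number as a block, and each animal left out in turn. The samples, comparisons, tests, gene lists, rule for named genes and these alternatives were fixed before the data were examined. A pair of alternatives was chosen after seeing the data, namely leaving out 4 arrays with a limma array weight below 0.25, and the mean of the 12 poly-A control probe sets as a covariate. Overlaps between comparisons with shared controls were set beside 100 simulations of unchanged groups. No gene is changed in these groups, so their shared counts cannot show how far shared controls raise the overlap of changed genes. Regroupings of the animals were limited to 100 splits per comparison.

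The tests were checked on simulated data with 200 of 17097 genes changed. Of genes changed 2-fold, 99% were recovered in the KO minus WT simulation, 95% in WT mice at 120 ppm and 1 week, and 90% in TG mice at 120 ppm and 4 weeks. Of genes changed 1.5-fold, 93%, 78% and 83% were recovered in these simulations, and over the 15 strain and exposure comparisons from 64% (WT at 40 ppm and 1 week) to 93%. It was 67% for KO at 120 ppm and 4 weeks, 70% for TG and 71% for KO at 120 ppm and 1 week. Each simulation drew its own 200 genes, with a spread per gene pooled over all groups. Differences between the exposure comparisons thus reflect the genes drawn, and a wider spread in a group was not simulated. Where fewer genes change, the adjustment is stricter and fewer would be recovered. The number of arrays limits the precision. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.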

Results

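Gene expression was measured in whole lungs of adult male C57BL/6 mice of 3 strains. The strains were wild type (WT), a knockout of Cyp2f2 (KO), and the knockout carrying the human genes CYP2F1, CYP2A13 and CYP2B6 (TG). Cyp2f2 encodes the main styrene-oxidising cytochrome P450 of mouse airway club cells. Mice breathed air (0 ppm) or styrene at 40 or 120 ppm, 6 h per day on 5 days per week, for 1 or 4 weeks, and the lungs were taken on the morning after the last exposure. Each of the 18 groups held 5 animals with 1 array each. Array medians lay between 4.42 and 4.86 log2, and a group mean below 4.42 is called dim. The highest correlation between 2 arrays was 0.997, and 0 pairs were identical. Changes are differences of log2 group means with the SE of the limma fit, n = 5 animals per group unless stated. For 4 arrays limma gave a weight below 0.25. They were KO animal 1 at 40 ppm and 4 weeks (0.0897), WT animal 3 at 120 ppm and 1 week (0.135), TG control animal 5 at 1 week (0.155) and KO control animal 3 at 1 week (0.211).

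The targeted gene was examined first. In unexposed mice, Cyp2f2 measured 13.27 ± 0.05 log2 in WT, 11.86 ± 0.16 in KO and 11.88 ± 0.14 in TG lungs (SD, n = 10 each). It was lower by 2.65-fold in KO than in WT (log2 difference -1.41, permutation p = 1e-05, the smallest that 100000 resamples can give) and by 2.62-fold in TG than in WT (-1.39, permutation p = 2e-05). KO and TG differed by 0.02 (permutation p = 0.80). Over all doses and times, the lowest of 30 WT animals was at 12.73 and the highest of 60 KO and TG animals at 12.28, so 0 of the 60 lay above a WT animal. A single probe set measured Cyp2f2, and its place relative to the deleted part is not given in the sources used here. The WT mean lay near the highest value of all arrays, 14.01, and the KO and TG means far above the array medians. The folds thus need not give the size of the mRNA loss.

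**Figure D1:**
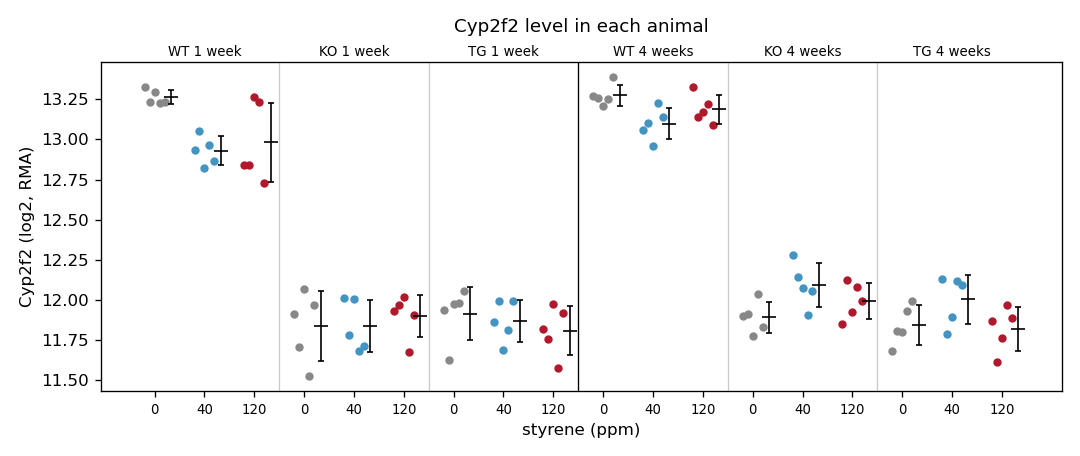
Cyp2f2 expression (log2) in each animal by strain, time and styrene dose, with the mean and SD of each group of 5 (points are animals). All 30 WT animals lie at 12.73 or above, and all 60 KO and TG animals at 12.28 or below.

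The first comparison asked which other genes differ between unexposed KO and WT lungs. Apart from Cyp2f2, the largest falls were in Pttg1, which encodes the securin of mitosis (7.56-fold, log2 change -2.92, SE 0.22, adjusted p = 6.2e-18), and in the carboxylesterases Ces1f (5.73-fold, -2.52, SE 0.27) and Ces1g (3.11-fold, -1.64, SE 0.15). The KO means of Ces1f (4.35) and Ces1g (3.58) were dim, as were those of Cd1d2 and Fetub and the WT mean of Tmod4 named next, so these folds compare with dim values. Gpx2, a glutathione peroxidase (2.30-fold, -1.20, SE 0.14), and Nqo1, a quinone reductase (1.82-fold, -0.87, SE 0.13), fell too, as did 5830417I10Rik, Cdk5rap1, Acsm1 and Fetub. Lrmda rose 3.57-fold (1.84, SE 0.11, adjusted p = 2.8e-22), with all 10 KO animals above every WT animal. Tmod4, an actin-capping protein of muscle (2.15-fold, 1.10, SE 0.21), Lmbr1 (1.96-fold, 0.97, SE 0.16), Cfl2 (1.75-fold, 0.81, SE 0.14), Cd1d2 (0.76), the Langerhans cell lectin Cd207 (0.74), Zfp354a (0.65) and Tnip1 (0.56) also rose.

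Among 24 measured genes of the Nrf2 and glutathione list, 3 fell in KO lungs (Gpx2, Nqo1 and Gsta2 at -0.63, SE 0.15), or 11 when adjusted over the list alone, with a median of -0.15 (list adjusted p = 0.0085). Of 25 xenobiotic-metabolising enzymes, 5 fell, among them Ces1g, Cyp1b1 (-0.73, SE 0.15), Ugt1a6a (-0.49, SE 0.07) and Aldh1a7 (-0.32, SE 0.06), or 9 when adjusted over the list alone (median -0.05, list adjusted p = 0.015). Of 15 dendritic cell and MHC class II genes, 0 passed in limma over all genes, and 11 rose when adjusted over the list alone, with a median of 0.24 (list adjusted p = 0.031). The largest values were Ccl17 (0.65, SE 0.19), Cd209a (0.44), Ccl22 (0.34) and Itgae (0.34). Near Cyp2f2, 1 of 19 listed neighbours fell, Mia (-0.79, SE 0.13). Of 11 genes known to differ between the C57BL/6J and C57BL/6N substrains, Wdfy1 fell (-0.85, SE 0.19, adjusted p = 0.012), and its adjusted p was 0.059 and 0.065 without KO control animals 1 and 4 at 4 weeks. The club cell markers Scgb1a1 (-0.03, SE 0.04, adjusted p = 0.89) and Scgb3a2 did not pass, and their WT control means of 13.8 and 13.3 at 1 week lay near the highest value of all arrays, 14.01. In all, 13 genes were higher and 34 lower in KO than in WT lungs, 26 of the 47 by over 1.5-fold. Fitted with the poly-A covariate, 75 genes passed, and 143 with array weights.

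In unexposed TG lungs, Ces1f (6.28-fold, log2 change -2.65, SE 0.27), Ces1g (3.66-fold, -1.87, SE 0.15), the neutrophil chemokine Cxcl1 (3.09-fold, -1.63, SE 0.24), the complement inhibitor Cd59a (2.63-fold, -1.39, SE 0.15), Gpx2 (2.34-fold, -1.22, SE 0.14) and Nqo1 (2.06-fold, -1.04, SE 0.13) were below WT. The TG means of Ces1f (4.22), Ces1g (3.34), Cxcl1 (2.86) and Camk2b (3.81) were dim. Cdk5rap1, Camk2b (-0.96, SE 0.13), Efcab7 and Acsm1 were lower too. Lrmda (3.67-fold, 1.88, SE 0.11), Lmbr1 (1.00, SE 0.16), the mitochondrial iron carrier Slc25a37 (1.69-fold, 0.75, SE 0.08), Entpd4 (1.61-fold, 0.68, SE 0.08) and Nrn1 (0.64, SE 0.13) were above WT. Jchain, the joining chain of secreted antibodies, rose 3.01-fold (1.59, SE 0.35, adjusted p = 0.011), and its adjusted p was 0.070 and 0.098 without TG control animal 2 at 1 week and without TG control animal 3 at 4 weeks. Of 24 Nrf2 and glutathione genes, 2 fell, or 11 when adjusted over the list alone (median -0.17, list adjusted p = 0.039). Of 25 xenobiotic enzymes, 4 fell, or 6 adjusted over the list alone (median -0.07, list adjusted p = 0.048). Mia fell as in KO lungs (-0.81, SE 0.13), and the dendritic cell list did not pass (adjusted p = 0.19 with an estimated correlation). In all, 12 genes were higher and 37 lower in TG than in WT lungs. The count of 49 was 82 without TG control animal 1 at 1 week, 98 without TG control animal 1 at 4 weeks 87 without the 4 arrays of low weight, 208 with array weights, 101 with the poly-A covariate and 80 with the replicate block.

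Between TG and KO lungs, Pttg1 was 7.04-fold higher in TG (2.82, SE 0.22, adjusted p = 1.2e-16). Erdr1 (3.92-fold, 1.97, SE 0.37), 5830417I10Rik (1.27), Entpd4 (0.69, SE 0.08), Slc25a37 (0.66, SE 0.08) and Mat2b (0.32, SE 0.05) were higher. Cxcl1 (2.54-fold, -1.34, SE 0.24), Cd59a (-0.81, SE 0.15), Cfl2 (-0.75), Cd1d2 (-0.72), the steroid hydroxylase Cyp3a13 (-0.64, SE 0.13, adjusted p = 0.0078) and Tnip1 (-0.50) were lower, and Cyp3a13 had an adjusted p of 0.053 without TG control animal 5 at 1 week. Of 21 PPAR target and fatty acid oxidation genes, 0 passed in limma and 6 were higher when adjusted over the list alone (median 0.13, list adjusted p = 0.030), with Pdk4 at 0.63 (SE 0.24), Acot1 at 0.50, Angptl4 at 0.47 and Acot2 at 0.46. Of the 11 substrain genes, Entpd4 was higher, and the list's adjusted p was 0.030 with a median of 0.02, which turned to -0.01 without the 4 arrays of low weight. Cxcl1 was dim in both strains, as was Cd1d2. In all, 9 genes were higher and 14 lower, and 7 passed when only these arrays were fitted, 54 with array weights and 43 with the poly-A covariate.

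KO and TG shared 3 genes above WT (Lrmda, Lmbr1 and Fam205a1) and 20 below, where independent lists would share 0.00912 and 0.0736. Both comparisons use the same 10 WT animals. In 100 simulations of unchanged groups, the median of shared genes was 0, and 1 simulation shared any, with 3149 genes. The correlation of changes across genes, which are not independent replicates, was 0.66, against 0.46 in the simulations, and the covariance was 0.0107 against 0.00525. With the WT animals split 5 and 5, the medians over 20 splits were 2 genes above, 10 below and a covariance of 0.00651.

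**Figure D2:**
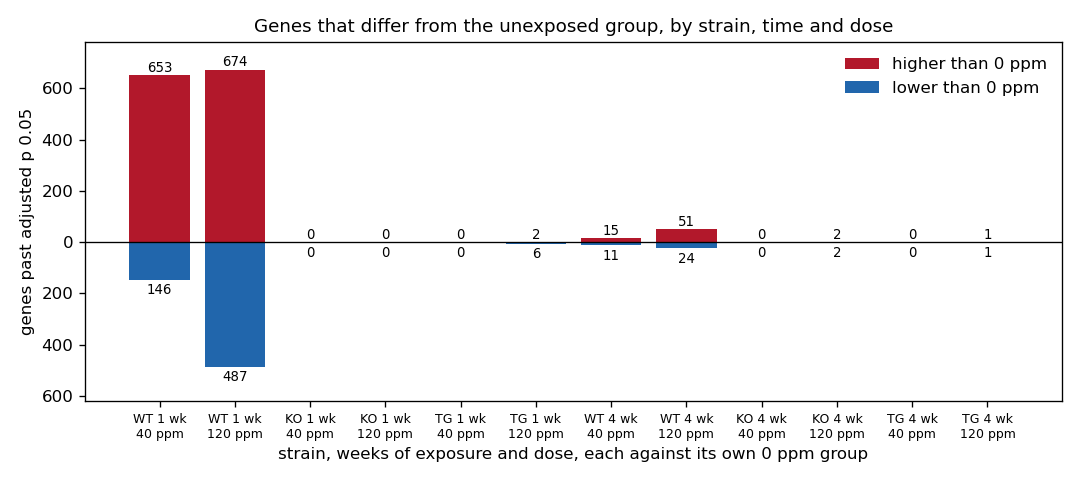
Genes that differed from the unexposed group (limma, adjusted p under 0.05) in each strain, time and dose, as bars of counts with higher genes in red and lower genes in blue. WT lungs had 799 and 1161 such genes after 1 week and 26 and 75 after 4 weeks, and no KO or TG group had more than 8.

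After 1 week at 40 ppm, the lists of cell cycle and sterol synthesis genes rose in WT lungs, and single genes of the circadian clock were among the largest changes. Dbp, a clock-output transcription factor, rose 10.3-fold (3.36, SE 0.43, adjusted p = 2.4e-08), while the clock activators Arntl (4.85-fold, -2.28, SE 0.29) and Npas2 (3.36-fold, -1.75, SE 0.29) fell. The neutrophil surface protein gene Cd177 (8.53-fold, 3.09, SE 0.41), Agr2, a disulfide isomerase of mucous cells (6.99-fold, 2.81, SE 0.47), the hormone gene Ghrl (6.39-fold, 2.68, SE 0.29) and Wfdc3 (5.36-fold, 2.42, SE 0.22) rose. The lipid-peroxide hydrolase Pon1 (5.38-fold, -2.43, SE 0.20, adjusted p = 9.1e-16), the glycoprotein receptor subunit Asgr1 (5.30-fold, -2.41, SE 0.32) and Spon2 (-1.62, SE 0.32) fell. All 5 exposed animals lay beyond every control animal for each of these genes except Spon2, where 4 did. Control means of Cd177 and Ghrl and the exposed mean of Asgr1 were dim.

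Of 44 measured cell cycle genes, 38 rose at 40 ppm, or 42 when adjusted over the list alone, with a median of 1.11 (list adjusted p = 0.0012). Cdc20 rose 4.85-fold (2.28, SE 0.30), Cdk1 4.55-fold (2.18, SE 0.27), Birc5 4.01-fold (2.00, SE 0.28), Aurka 3.79-fold (1.92, SE 0.26) and the proliferation marker Mki67 2.49-fold (1.32, SE 0.34). Sterol and fatty acid synthesis genes rose in 10 of 21, or 18 adjusted over the list alone (median 0.53, list adjusted p = 0.042), among them Fdps (0.97, SE 0.19), Mvd (0.95, SE 0.22), Cyp51 (0.80) and Fasn (0.68). Of 16 alveolar type II cell markers, 9 rose, or 10 adjusted over the list alone (median 0.23, list adjusted p = 0.028), led by Il33 (1.15, SE 0.21), Muc1 (0.71) and Chil1 (0.64). Of 19 endothelial markers, Emcn (-0.50, SE 0.16) and Tek (-0.35, SE 0.10) fell, or 6 adjusted over the list alone (median -0.31, list adjusted p = 0.030). Of 17 clock genes, 6 rose and 3 fell, or 8 and 5 adjusted over the list alone (adjusted p = 0.52 with an estimated correlation). The list test asks for a shift in the same direction, so clock genes that rise and fall partly cancel in it. A high p of the clock list, here and below, thus does not show that the clock genes were unchanged. Of 24 Nrf2 and glutathione genes, 5 rose, or 9 adjusted over the list alone, among them Akr1b8 (0.69, SE 0.17), Nqo1 (0.66, SE 0.18) and Gclc (0.50), with a list adjusted p of 0.67. The p53 targets Cdkn1a (-0.88, SE 0.27), Fas (-0.61) and Btg2 (-0.50) fell (list adjusted p = 0.49). The list of T and NK cell markers had a median of -0.19 (list adjusted p = 0.54) and that of B and plasma cells -0.26 (list adjusted p = 0.49).

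Cyp2f2 itself fell 1.26-fold in WT lungs at 40 ppm and 1 week (-0.33, SE 0.09, adjusted p = 0.013) and 1.22-fold at 120 ppm (-0.28, SE 0.09, adjusted p = 0.038). Scgb1a1 was at -0.16 (SE 0.05, adjusted p = 0.073) and -0.11 (adjusted p = 0.21), and Scgb3a2 at -0.04 and -0.02, which did not pass. At 40 ppm, 653 genes were higher and 146 lower, 380 of the 799 by over 1.5-fold. The count was 472 without WT control animal 2, 1385 without the 4 arrays of low weight, 1465 with the poly-A covariate and 2446 with array weights.

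After 1 week at 120 ppm, WT lungs again showed higher cell division genes and lower Pon1. Dbp rose 10.7-fold (3.42, SE 0.43, adjusted p = 1.1e-08), and Arntl (5.40-fold, -2.43, SE 0.29) and Npas2 (4.51-fold, -2.17, SE 0.29) fell. The mitotic kinase gene Pbk (5.28-fold, 2.40, SE 0.25), Cdk1 (5.12-fold, 2.36, SE 0.27, adjusted p = 7.8e-10), Cep55 (4.42-fold, 2.14, SE 0.29), Tk1 and Birc5 rose. Retnla, a secreted resistin-like protein (4.57-fold, 2.19, SE 0.31), Ces1g (4.43-fold, 2.15, SE 0.21, adjusted p = 4.8e-12), Ghrl (2.39), Agr2 (2.39), Cd177 (2.33) and Wfdc3 (2.09) rose as well. Pon1 fell 4.47-fold (-2.16, SE 0.20, adjusted p = 2.8e-13), and the vasodilator peptide gene Adm (3.46-fold, -1.79, SE 0.28), Asgr1 (-1.75), Spon2 (-1.38), Igfbp3 (2.51-fold, -1.33, SE 0.26), Lonrf3 and the clock repressor Nfil3 (-1.08, SE 0.26) fell. Nr4a3 fell on its brightest probe set (-1.73, SE 0.31), and the median of its 3 probe sets was at 0.09. Control means of Ghrl, Cd177, Cep55 and Tk1 and exposed means of Npas2 and Asgr1 were dim. The SD at 120 ppm was 1.24 for Cdk1, 0.93 for Ces1g and 0.94 for Pon1, against 0.42, 0.41 and 0.22 in controls. That of Dbp was 0.28 against 0.89. The limma SE pools the spread over all 18 groups, so for genes like the first 3 it and its p understate the spread here. The same holds for the strain and time differences that use this group.

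Of 44 cell cycle genes, 41 rose at 120 ppm, or 42 adjusted over the list alone, with a median of 1.31 (list adjusted p = 0.00026). The mean of these genes per animal, relative to the mean of all animals, was -0.16 ± 0.14 in WT controls, 0.98 ± 0.20 at 40 ppm and 1.13 ± 0.85 at 120 ppm (SD, n = 5). The 120 ppm animals ranged from 0.05 to 2.26, and the lowest was animal 3, whose array had a weight of 0.135 and the lowest median of all arrays, 4.42. Of 24 Nrf2 and glutathione genes, 8 rose, or 9 adjusted over the list alone, led by Nqo1 (2.17-fold, 1.12, SE 0.18), Akr1b8 (0.90, SE 0.17), Gpx2 (0.68) and Cbr3 (0.58), with a list adjusted p of 0.46. Of 17 clock genes, 8 rose and 4 fell, or 8 and 5 adjusted over the list alone (list adjusted p = 0.47). Endothelial markers fell in 5 of 19, or 9 adjusted over the list alone (list adjusted p = 0.10), with Ednrb at -0.54 (SE 0.14), Cldn5 at -0.50, Tek at -0.50 and Kdr at -0.47. Of 15 alveolar macrophage markers, only Ctsk (1.26, SE 0.26), Marco (0.98, SE 0.25) and Car4 (0.37) passed, and they rose (list adjusted p = 0.47). The neutrophil markers Lcn2 (1.51, SE 0.23) and Mmp8 (1.08) rose too, 2 of 13 on their list (list adjusted p = 0.61), and Lcn2 is also in the glucocorticoid and inflammation lists. Sterol synthesis genes rose in 6 of 21, or 9 adjusted over the list alone (list adjusted p = 0.47), led by Fdps (0.66), and alveolar type II markers in 6 of 16, or 7 adjusted over the list alone (list adjusted p = 0.19), led by Il33 (0.82). Of the p53 targets, Cdkn1a (-0.95, SE 0.27), Pmaip1, Btg2 and Xpc fell, while the list median of -0.03 turned to 0.03 when quantile normalization was applied again. T and NK cell markers had a median of -0.21 (list adjusted p = 0.81), B and plasma cell markers -0.17 (list adjusted p = 0.78) and thymocyte genes -0.05 (list adjusted p = 0.92).

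At 120 ppm and 1 week, 674 genes were higher and 487 lower in WT lungs, 430 of the 1161 by over 1.5-fold. Quantile normalization applied again gave 1010 higher and 382 lower. Fitted on only these 10 arrays, 36 genes passed. The count was 628 without animal 5 at 120 ppm, 1844 without animal 3 at 120 ppm, 633 without control animal 2, 2800 without the 4 arrays of low weight and 3123 with the poly-A covariate.

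**Figure D3:**
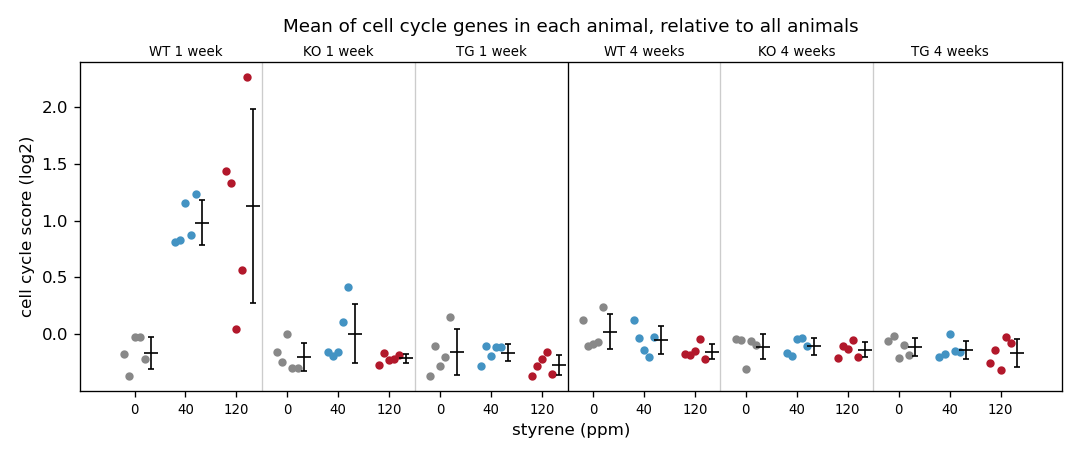
Mean log2 level of the cell cycle genes in each animal, relative to the mean over all animals, by strain, time and dose, with the mean and SD of each group of 5. WT means are 0.98 at 40 ppm and 1.13 at 120 ppm after 1 week and -0.05 and -0.15 after 4 weeks.

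The 40 and 120 ppm comparisons of WT lungs at 1 week shared 457 higher and 126 lower genes, where independent lists would share 25.7 and 4.16, and simulated unchanged groups with the same controls shared 0 in 100 simulations. The covariance of the changes across genes was 0.0551 against 0.00979 in the simulations, and the correlation 0.87 against 0.46. With the controls split 2 and 3, the medians over 10 splits were 163.5 higher genes, 27 lower genes and a covariance of 0.0475. Tested directly, 0 genes differed between 120 and 40 ppm at 1 week in limma, with 873 at an unadjusted p under 0.05, and 6 passed without animal 4 at 120 ppm. The smallest p were those of Pank1 (-0.44, SE 0.10), Ccna1 (-0.72, SE 0.17) and 5430427M07Rik (0.53, SE 0.13, dim at both doses), with adjusted p = 0.43.

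After 4 weeks at 40 ppm, WT lungs kept higher Dbp (6.65-fold, 2.73, SE 0.43) and lower Npas2 (3.54-fold, -1.82, SE 0.29) and Arntl (3.46-fold, -1.79, SE 0.29) than controls. Ces1g rose 5.59-fold (2.48, SE 0.21, adjusted p = 1.1e-14), and the thrombin inhibitor Serpind1 2.66-fold (1.41, SE 0.17). Gp2, a glycoprotein of epithelial M cells, rose 6.16-fold (2.62, SE 0.54, adjusted p = 0.0073), with adjusted p of 0.057 without control animal 5 and 0.051 without animal 1 at 40 ppm. The control mean of Gp2 and the exposed mean of Npas2 were dim. Of 17 clock genes, 3 rose and 3 fell, or 9 and 5 adjusted over the list alone (list adjusted p = 0.55). Of 44 cell cycle genes, 0 passed in limma (median -0.07). In all, 15 genes were higher and 11 lower, with 809 at an unadjusted p under 0.05. The count of 26 was 17 without control animal 1, 17 without control animal 3, 12 without animal 4 at 40 ppm, 12 with dim genes left out, 57 with the poly-A covariate and 41 without the 4 arrays of low weight.

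After 4 weeks at 120 ppm, Dbp was 10.1-fold above controls in WT lungs (3.33, SE 0.43, adjusted p = 9.6e-08), and the clock genes Nr1d2 (1.37, SE 0.30) and Per3 (1.27, SE 0.21) rose, while Arntl (5.95-fold, -2.57, SE 0.29), Npas2 (4.67-fold, -2.22, SE 0.29) and Nfil3 (3.10-fold, -1.63, SE 0.26) fell. Ces1g rose 7.24-fold (2.85, SE 0.21, adjusted p = 7.2e-18), Gp2 7.06-fold (2.82, SE 0.54), Tex11 3.42-fold (1.77, SE 0.32) and Serpind1 3.33-fold (1.74, SE 0.17), and all 5 exposed animals lay above every control for each. Sptssb (1.36), a subunit of sphingolipid synthesis, and Tspan4 (1.22) rose too. Pon1 fell 2.27-fold (-1.18, SE 0.20), and Spon2 (-1.64), Asgr1 (-1.55), the cell cycle inhibitor Cdkn1a (2.39-fold, -1.26, SE 0.27), Mfsd4a and Lonrf3 fell. Control means of Gp2 and Tex11 and exposed means of Npas2, Asgr1 and Mfsd4a were dim. Of 17 clock genes, 6 rose and 3 fell, or 10 and 5 adjusted over the list alone (median 0.55, list adjusted p = 0.16). Of 24 Nrf2 and glutathione genes, Nqo1 (1.70-fold, 0.76, SE 0.18) and Cbr3 (0.71, SE 0.14) rose, or 5 adjusted over the list alone (list adjusted p = 0.23). Cell cycle genes did not pass, with a median of -0.19 (list adjusted p = 0.63) and Mki67 at -0.73 (SE 0.34, adjusted p = 0.79).

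In all, 51 genes were higher and 24 lower in WT lungs at 120 ppm and 4 weeks, 57 of the 75 by over 1.5-fold. The count was 48 without animal 2 and 47 without animal 4 at 120 ppm, 118 without the 4 arrays of low weight, 116 with the poly-A covariate and 209 with array weights. The 40 and 120 ppm comparisons at 4 weeks shared 14 higher and 11 lower genes, where independent lists would share 0.0447 and 0.0154 and the simulations with shared controls 0. The covariance was 0.0196 against 0.0102 in the simulations, and with the controls split 2 and 3 the medians over 10 splits were 5 and 2 genes and a covariance of 0.0116. Tested directly, 0 genes differed between 120 and 40 ppm at 4 weeks in limma, with 365 at an unadjusted p under 0.05, and 1 passed without animal 1 or 3 at 40 ppm, without animal 3 at 120 ppm, or with quantile normalization applied again. The smallest p was that of Kng1 (0.66, SE 0.14, adjusted p = 0.098), dim at both doses (3.37 and 2.70).

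The difference between times in the WT 120 ppm change was tested next. The change of Pbk was lower at 4 weeks by 2.97 log2 units, given as -2.97 (SE 0.36, adjusted p = 5.9e-08), followed by Cdk1 (-2.77, SE 0.38), Cep55 (-2.73), Ccna2 (-2.58), Top2a (-2.45) and Mki67 (-2.22, SE 0.48). Of 44 cell cycle genes, 34 had a lower change at 4 weeks, or 42 adjusted over the list alone (median -1.61, list adjusted p = 5.3e-06). Serpind1 (1.10, SE 0.24) and Gm8126 (1.31, SE 0.25) had a higher change at 4 weeks. In all, 23 genes had a higher and 128 a lower change. The count of 151 was 296, 269 and 90 without WT animals 3, 4 and 5 at 120 ppm and 1 week, 49 with dim genes left out, and 0 with only these arrays fitted. The 120 ppm comparisons at 1 and 4 weeks, which share no animals, had 36 higher and 18 lower genes in common, where independent lists would share 2.01 and 0.684.

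**Figure D4:**
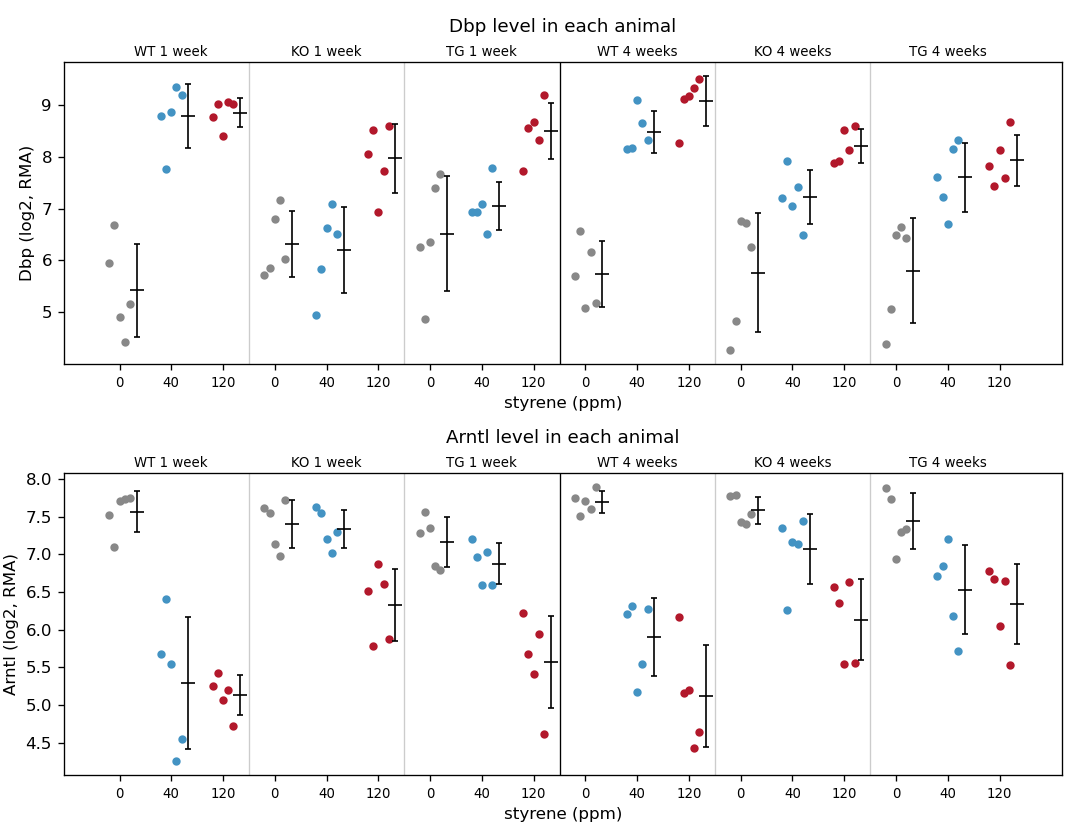
Clock index of each animal in log2 units by strain, time and dose, which is the mean of Dbp, Tef, Hlf, Per3 and Nr1d2 minus the mean of Arntl, Npas2 and Nfil3, with the mean and SD of each group of 5. From 0 to 120 ppm the WT mean moves from 0.48 to 3.96 at 1 week and from 0.64 to 4.41 at 4 weeks, and the KO mean from 0.96 to 2.93 and from 0.91 to 3.47.

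KO lungs were compared with their own controls in the same way. After 4 weeks at 120 ppm, Dbp rose 5.42-fold (2.44, SE 0.43, adjusted p = 0.0019) and the related factor Tef 1.68-fold (0.75, SE 0.16, adjusted p = 0.033), while Npas2 (3.30-fold, -1.72, SE 0.29) and Arntl (2.73-fold, -1.45, SE 0.29) fell, and these were the 4 genes that passed. The exposed mean of Npas2 was dim. Of 17 clock genes, 2 rose and 2 fell, or 11 and 3 adjusted over the list alone (median 0.46, list adjusted p = 0.0042). This p does not show a larger clock shift than in WT lungs. At 120 ppm and 4 weeks the clock index rose by 2.56 in KO and by 3.77 in WT. All 5 exposed animals lay beyond every control for each of the 4 genes. The count of 4 was 1 without control animal 1, 2 without control animals 2 or 5, 2 without animals 3 or 5 at 120 ppm, 2 with only these arrays fitted and 15 with array weights. The calls of Dbp, Arntl and Tef ended in 1, 5 and 6 of the 10 fits that leave out an animal, with adjusted p up to 0.39.

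In the other KO groups, 0 genes passed in limma. At an unadjusted p under 0.05 there were 611 genes at 40 ppm and 881 at 120 ppm after 1 week, and 537 at 40 ppm after 4 weeks. At 120 ppm and 1 week, Npas2 was at -1.24 (SE 0.29, adjusted p = 0.26), Hoxd1 at 0.34 and Cdhr1 at -0.42, both dim in both groups, and Dbp at 1.65 (SE 0.43, adjusted p = 0.29). At 40 ppm and 1 week, the smallest p was that of the secreted protein gene Bpifa2 (1.12, SE 0.23, adjusted p = 0.10, dim in both groups), and the fibroblast and matrix list had a median of 0.29 (adjusted p = 0.052 with an estimated correlation). Cell cycle genes at 40 ppm had a median of 0.19 (list adjusted p = 0.59). At 40 ppm and 4 weeks, the smallest p were those of the liver-enriched genes Cyp3a11 (1.36, SE 0.30), Alb (1.51, SE 0.34) and Serpina1c (1.44, SE 0.33), with adjusted p = 0.19, and their control means of 2.65, 3.89 and 2.61 were dim. Alb was at 6.43 and 8.12 in animals 3 and 4 of this group and between 4.11 and 4.18 in the others. Cyp3a11 (4.82 and 6.90) and Serpina1c (4.91 and 7.15) were highest in the same animals. At 120 ppm and 1 week, 7 genes passed without control animal 1, 3 without control animal 2 and 1 without animal 2 at 120 ppm. At 40 ppm, 1 passed at 1 week without animal 1 or 2. At 4 weeks 4, 8 and 6 passed without animals 1, 2 and 5 at 40 ppm, all of them higher, and 10 with array weights. Animals 1, 2 and 5 had low Alb, so animals 3 and 4 weigh more in the fits without them.

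In TG lungs at 120 ppm and 1 week, Npas2 (3.89-fold, -1.96, SE 0.29, adjusted p = 2.5e-05), Arntl (3.02-fold, -1.60, SE 0.29, adjusted p = 0.0035) and Nfil3 (2.29-fold, -1.20, SE 0.26) fell, and Dbp (3.94-fold, 1.98, SE 0.43, adjusted p = 0.044) and Per3 (2.00-fold, 1.00, SE 0.21) rose. The histone genes H3c15 (-0.81, SE 0.17) and H3c14 (-0.57, SE 0.12) and Hemk1 (-0.43, SE 0.09) fell, so that 2 genes were higher and 6 lower. The exposed mean of Npas2 was dim. Of 17 clock genes, 2 rose and 3 fell, or 6 and 4 adjusted over the list alone (list adjusted p = 0.90). The club cell list had a median of -0.64 with 0 genes passing in limma (list adjusted p = 0.90), with Reg3g at -2.55 (SE 0.96) and Muc5b at -1.61 (SE 0.52). The count of 8 was 2 without control animal 2 or 3 or animal 2 or 5 at 120 ppm, 5 without control animal 5, 13 without animal 4 at 120 ppm, and 3 with the poly-A covariate. Npas2 passed in each fit that leaves out an animal, while the calls of Dbp, Per3, Nfil3, H3c14, H3c15 and Hemk1 ended in 6, 5, 8, 5, 8 and 7 of these 10 fits and that of Arntl in 1 (adjusted p = 0.10).

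In TG lungs at 120 ppm and 4 weeks, Npas2 fell (2.69-fold, -1.43, SE 0.29) and Dbp rose (4.35-fold, 2.12, SE 0.43), both with adjusted p = 0.036, and Kcns3 was at 0.53 (SE 0.12, adjusted p = 0.16). The count of 2 was 1 without control animal 3 or 4, 1 without control animal 1, where another gene passed and neither Dbp nor Npas2 did, and 0 without control animal 2 or 5 or animal 1, 3, 4 or 5 at 120 ppm. Quantile normalization applied again gave 0 higher and 1 lower, and array weights gave 106. At 40 ppm, 0 genes passed in limma after 1 or 4 weeks, with 757 and 1278 at an unadjusted p under 0.05. The smallest p were those of Atcayos (-0.49) and 9030612E09Rik (-0.38), dim in both groups, and L1cam (0.43) at 1 week and of Dcaf4 (0.56), Sdha (0.26) and Rnaseh2b (0.62) at 4 weeks, and Dbp was 3.47-fold above controls at 4 weeks without passing (SE 0.43 log2, adjusted p = 0.22). Without control animal 3 at 1 week, 1 gene passed, as without control animal 1 at 4 weeks, where array weights gave 73 and the poly-A covariate 22.

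Whether strains differed in the 120 ppm change was tested directly. After 1 week, the change of cell division genes was lower in KO than in WT lungs, with Cdk1 at -2.58 (SE 0.38, adjusted p = 4.3e-06) as the KO change minus the WT change. Of 44 cell cycle genes, 33 had a lower change in KO, or 39 adjusted over the list alone (median -1.26, list adjusted p = 0.0047). The change was also lower in KO for Gp2 (-3.69, SE 0.76), Agr2 (-3.37, SE 0.66), Ghrl (-2.94, SE 0.41), Cd177 (-2.93, SE 0.58), Nqo1 (-1.09, SE 0.26) and Akr1b8 (-0.97, SE 0.24). It was higher in KO for Pon1 (2.07, SE 0.28, adjusted p = 5.6e-07) and Asgr1 (2.25, SE 0.46), and for 2 of 19 endothelial markers, Kdr (0.58) and Tek (0.53), or 8 adjusted over the list alone (median 0.44, list adjusted p = 0.048). Gp2, Ghrl and Cd177 were dim in WT controls and in KO lungs at 120 ppm, and Asgr1 in WT lungs at 120 ppm, so these differences compare with dim values. The Dbp change did not pass (-1.77, SE 0.61, adjusted p = 0.10), nor did those of Mki67 (-1.28, SE 0.48, adjusted p = 0.16) and Cyp2f2 (0.35, SE 0.13, adjusted p = 0.13). In all, 104 genes had a higher and 301 a lower change. The count of 405 was 186 without WT control animal 2, 213 without KO control animal 3, 257, 828, 671 and 158 without WT animals 2, 3, 4 and 5 at 120 ppm, and 235 and 269 without KO animals 3 and 4 at 120 ppm. It was 6 with only these arrays fitted and 1515 with the poly-A covariate.

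After 1 week, TG minus WT changes were lower for Agr2 (-3.38, SE 0.66), Retnla (-3.26, SE 0.44), Cdk1 (-2.78, SE 0.38, adjusted p = 5.0e-07) and Ghrl (-2.67, SE 0.41), and higher for Pon1 (2.08, SE 0.28) and Asgr1 (1.92, SE 0.46). The TG minus WT change was also lower for Clca1, a secreted protein of mucous cells (-6.73, SE 1.40, adjusted p = 0.0012, and -3.51 with the median of its probe sets), although its change passed neither in WT (2.59, adjusted p = 0.105) nor in TG (-4.15, adjusted p = 0.127). Clca1 means went from 3.71 (dim) to 6.30 in WT and from 7.32 to 3.17 (dim) in TG, and Ghrl was dim in TG lungs and WT controls. Of 44 cell cycle genes, 34 had a lower change in TG, or 41 adjusted over the list alone (median -1.38, list adjusted p = 0.012). Of 24 Nrf2 and glutathione genes, 8 had a lower change, or 11 adjusted over the list alone, among them Nqo1 (-1.12, SE 0.26) and Gpx2 (-1.02, SE 0.27), with a list adjusted p of 0.49. The changes of Dbp (-1.44, SE 0.61, adjusted p = 0.15) and Mki67 (-1.50, SE 0.48, adjusted p = 0.054) did not pass. In all, 200 genes had a higher and 584 a lower change. The count of 784 was 337 without WT control animal 2, 1208 and 300 without TG control animals 1 and 5, 496, 1858 and 418 without WT animals 2, 3 and 5 at 120 ppm, and 519, 1229 and 447 without TG animals 1, 3 and 5 at 120 ppm. It was 23 with only these arrays fitted. Between TG and KO, 0 genes passed in limma after 1 week, with 504 at an unadjusted p under 0.05, and 1 passed without TG control animal 1 or 2 or KO animal 5 at 120 ppm.

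After 4 weeks at 120 ppm, the changes of Ces1g and Serpind1 were lower in both other strains than in WT. The KO minus WT changes were -2.69 for Ces1g (SE 0.30, adjusted p = 1.6e-09), -1.87 for Serpind1 (SE 0.24, adjusted p = 1.3e-07) and 1.35 for Pon1 (SE 0.28, adjusted p = 0.030), and these 3 genes passed. The TG minus WT changes were -2.71 for Ces1g (SE 0.30), -1.82 for Serpind1 (SE 0.24), -1.17 for Gm8126 (SE 0.25, dim but for WT at 120 ppm) and -0.99 for Kcnmb4 (SE 0.21). The change of Kng1, which encodes kininogen and was dim in all groups compared, was 2.01-fold lower (SE 0.19 log2, adjusted p = 0.0084, and 0.078 without WT animal 2 at 120 ppm), and these 5 genes passed. With the median of its 2 probe sets the Kng1 difference was -0.57 (limma adjusted p = 0.082). Fitted on only these arrays, its adjusted p was 0.075. The calls of Gm8126 and Kcnmb4 ended in 13 and 16 of 20 fits that leave out an animal. Ces1g measured 5.23 ± 0.24, 7.71 ± 0.30 and 8.09 ± 0.39 in WT lungs at 0, 40 and 120 ppm (SD, n = 5). Between TG and KO, 0 genes passed in limma, with 359 at an unadjusted p under 0.05. All KO and TG group means of Ces1g lay between 3.20 and 3.71, below every array median, and Serpind1 and Ces1g are left out with the dim genes. With dim genes left out, 0 passed in the KO and 0 in the TG comparison with WT. The call of Pon1 ended in 11 of 20 fits that leave out an animal, with adjusted p up to 0.15. The TG count of 5 was 3 without WT control animal 2, 4 or 5, TG control animal 3, 4 or 5, WT animal 4 or TG animal 1 at 120 ppm, and 2 without WT animal 2 at 120 ppm.

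**Figure D5:**
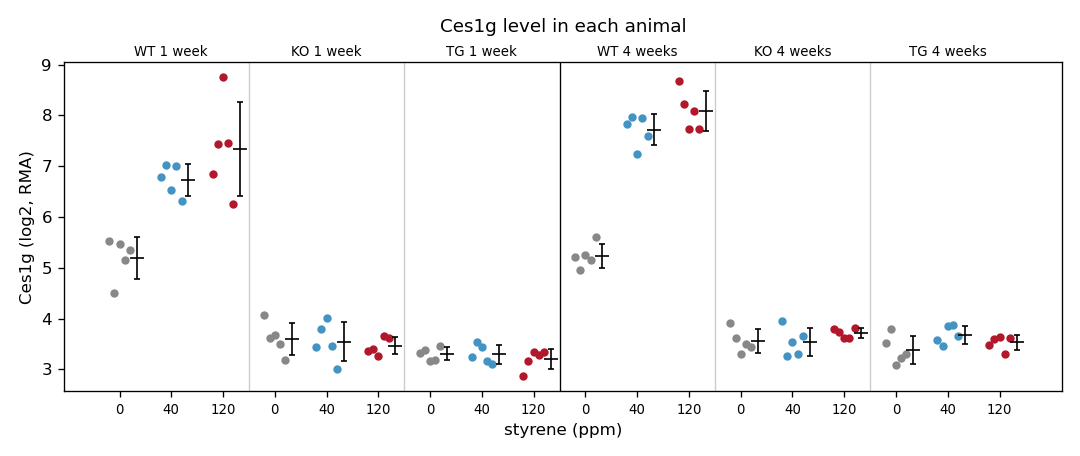
Ces1g expression (log2) in each animal by strain, time and styrene dose, with the mean and SD of each group of 5. After 4 weeks the WT means are 5.23, 7.71 and 8.09 at 0, 40 and 120 ppm, and all KO and TG group means lie between 3.20 and 3.71.

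Over the 15 strain and exposure comparisons and 36 lists, 155 of 540 list tests passed at the preset correlation and 13 with an estimated correlation. The glucocorticoid marker Fkbp5 and the clock gene Per1 did not pass in any of the 12 exposure comparisons.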

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

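Chosen after the results were seen were the splits of the animals, the tests on array quality, RNA amount, lymphoid genes and collection time, and the test of which strain genes neighbour each other.

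A sample far from the others of its group was found in 9 of the 198 groups of values tested, where chance gives about 1 in 20. Cyp2f2 was at 11.63 in TG control animal 2 at 1 week (nearest animal 11.94), Scgb1a1 at 13.57 in WT animal 3 at 40 ppm and 4 weeks (13.75), and Scgb3a2 at 13.49 in TG animal 5 at 40 ppm and 4 weeks (13.33). Arntl was at 6.26 in KO animal 2 (7.13) and Pttg1 at 11.30 in KO animal 5 (9.41), both at 40 ppm and 4 weeks. Over all doses and times Pttg1 ran from 8.71 to 11.42 in the 30 KO animals, 5 of them above 11, and from 11.68 to 12.16 in the 60 WT and TG animals, while the unexposed KO animals reached 9.57 at most. The KO group SD was 1.19 at 40 ppm and 1 week and 1.30 at 120 ppm and 4 weeks. Lrmda was at 7.59 in TG control animal 5 at 1 week (6.90). The cell cycle mean was -0.303 in KO control animal 3 at 4 weeks (-0.0958) and 0.00156 in TG animal 3 at 40 ppm and 4 weeks (-0.151). The clock index was 1.79 in WT control animal 2 at 1 week (0.371).

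The 120 ppm change differed between KO and WT in 405 genes at 1 week and 3 at 4 weeks, between TG and WT in 784 and 5, and between times within WT in 151, each by a test of the difference in limma. Outside the genes tested, 16139 probe sets had no single listed gene. Of these, 19, 38 and 24 differed between KO and WT, TG and WT, and TG and KO lungs. With exposure for 1 week, 254 changed in WT lungs at 40 ppm (188 higher and 66 lower) and 1093 at 120 ppm (246 higher and 847 lower). The excess of lower probe sets at 120 ppm may depend on normalization, as the higher and lower counts of the tested genes did. Its cause was not tested. In WT lungs 8 and 26 changed after 4 weeks. There was 1 each in TG at 120 ppm and 1 week, KO at 120 ppm and 4 weeks, and TG at 120 ppm and 4 weeks.

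Cell cycle genes rose in WT lungs after 1 week. Without the 4 arrays of low weight 43 of 44 genes were higher at 120 ppm, so the rise does not rest on these arrays. Among the groups compared, only WT animal 3 at 120 ppm had such an array, and its cell cycle mean was the lowest (0.05). Leaving it out could thus hardly lower the count, and poor quality in other arrays was not tested. With the poly-A covariate 41 genes were higher. The poly-A means of controls and 120 ppm lay close together (6.71 ± 0.23 and 6.60 ± 0.30, SD). The covariate could thus remove little, and unequal amounts of sample RNA are not excluded by it. Lymphocytes or thymus tissue in the exposed lungs cannot be told apart from division of lung cells by these values. The mean change of 39 T and NK cell, B cell and thymus genes was -0.16 (SE 0.12) at 120 ppm and -0.19 (SE 0.12) at 40 ppm, but 14 of them lie above the median gene in unexposed WT lung, 1 is in another list, and their levels in resident cells would hide a small share. The most abundant, Xbp1, Gzma, Ccl5 and Cd2, went from 11.93 to 11.81, 8.77 to 8.29, 8.17 to 7.54 and 7.85 to 7.98 (n = 5). A response to styrene that depends on Cyp2f2 stays a hypothesis, as strain differences other than Cyp2f2 were not separated from it.

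For the clock genes, which shifted with dose, a time of collection that differed with dose but not with strain is argued against at 40 ppm and 1 week, where the clock index shifted by 3.23 in WT, 0.07 in KO and 0.70 in TG lungs (permutation p = 0.00202 for WT against KO, n = 5). Over all 12 pairs of strains, times and doses, Holm-adjusted exact p were 0.023 for this pair, 0.040 for WT against TG at 40 ppm and 1 week, and 0.10 or more for the others. At 4 weeks the 40 ppm shifts were 2.85, 1.06 and 1.91 in WT, KO and TG. Every gene of the index passed in WT lungs at 120 ppm at both times, which can favour a larger shift in WT. The p of the index do not allow for that, so the argument is weaker than they read. A time of collection that differed between groups in any way cannot be told apart from an effect of styrene, since no time is given per animal, and the index rose in 6 of 6 comparisons of 120 ppm with 0 ppm (3.48 and 3.77 in WT, 1.97 and 2.56 in KO, 2.67 and 2.33 in TG at 1 and 4 weeks). Within groups, the deviations of Dbp and Arntl were correlated over 90 animals (r = -0.73, rho = -0.80, permutation p = 1e-05 for both, the smallest that the resamples can give, the only correlation tested), and r was -0.75 without the 2 farthest animals. Animals of a group may thus have been at different clock phases.

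Genes that differed between unexposed strains lay near each other. In the gene order of GRCm38.p6, 24 of 47 genes between KO and WT had another such gene within 50 genes (random median 11, permutation p = 0.001), as had 22 of 49 between TG and WT (12, permutation p = 0.007) and 14 of 23 between TG and KO (2, permutation p = 0.0003). Stretches of DNA from another strain or substrain are a candidate explanation, with sets such as Mat2b, Nudcd2 and Pttg1, or Slc25a37 and Entpd4. Gene families such as Ces1 also lie together, and genes changed by exposure in WT lungs at 4 weeks gave 2 of 25 at 40 ppm (3, permutation p = 0.8) and 34 of 74 at 120 ppm (25, permutation p = 0.05). Sequence differences under the probes cannot be told apart, since a second bright probe set changed the same way for 16 of 20 genes (80%, exact binomial interval 56.3% to 94.3%, genes shared by KO and TG counted in both), and the rule that reads this interval was set after its value was seen.

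Other splits of the animals were tried, 100 per comparison with the real split included. As many genes in fewer than 5 of the 100 splits was read as excluding chance. By this reading chance is argued against for KO against WT (47 genes, as many in 1 split, highest other 11), TG against WT (49, 1 split, 17), TG against KO (23, 2 splits, 89), WT at 40 ppm at 1 week (799, 1 split, 157) and 4 weeks (26, 1 split, 3), and WT at 120 ppm and 4 weeks (75, 1 split, 11). KO at 120 ppm and 4 weeks (4, 4 splits, 4) and TG at 120 ppm and 4 weeks (2, 2 splits, 2) also pass this rule, but other splits reached the same counts. The differences in 120 ppm change between KO and WT at 1 week (405, 3 splits, 802) and 4 weeks (3, 3 splits, 17) and between TG and WT at 4 weeks (5, 4 splits, 66) pass the rule too. For these and for TG against KO, a few other splits gave more genes than the real split, so few splits do so but a structure of the samples beside the groups stays open.

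Chance is not excluded by the splits for WT at 120 ppm and 1 week (1161 genes, as many in 7 splits, highest other 2899), TG at 120 ppm and 1 week (8, 9 splits, 1594), the TG minus WT difference at 1 week (784, 11 splits, 5616) and the difference between times (151, 7 splits, 693). WT at 120 ppm and 1 week shared 36 higher and 18 lower genes with 4 weeks, from other animals. Independent lists would share 2.01 and 0.684. Genes that move together can raise shared counts without an effect of exposure, so this overlap does not decide on chance. Where 0 genes passed in limma, all 100 splits give as many by construction, which says nothing about chance, with highest other counts of 1 and 29 for KO at 40 and 120 ppm and 1 week (611 and 881 genes at an unadjusted p under 0.05), 2 for TG at 40 ppm and 1 week (757), and 4 and 4 for KO and TG at 40 ppm and 4 weeks (537 and 1278). For the TG minus KO difference they were 3952 at 1 week (504) and 2 at 4 weeks (359), and for 120 against 40 ppm in WT 525 at 1 week (873) and 1 at 4 weeks (365). Splits that give several times the real count point to a structure of the samples, or to single outlying arrays, and these were not told apart.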

How the results depend on the processing

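The number of animals and array signal over background limit what these comparisons can find, and the alternatives below moved several counts by more than 1.5 times. Without the 4 arrays of low weight and with the poly-A covariate, which were chosen after seeing the data, and for all others, the cause was not tested. Array weights are computed from the genes' own deviations, so an animal with a different response also gets a low weight.

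With dim genes left out, fewer genes were tested, and the counts were 12 (WT, 40 ppm, 4 weeks), 0 and 0 (KO and TG minus WT change at 4 weeks) and 49 (difference between times). Quantile normalization applied again gave 1 for TG at 120 ppm and 4 weeks and 1 for 120 against 40 ppm in WT at 4 weeks. With only the arrays compared, the spread comes from fewer arrays and from the compared groups alone, which were not told apart. The SD of the cell cycle mean was 0.85 in WT at 120 ppm and 1 week, against 0.20 at 40 ppm. Counts in this fit were 7 (TG against KO), 36 (WT, 120 ppm, 1 week), 2 and 2 (KO and TG, 120 ppm, 1 week), 2 and 0 (KO and TG, 120 ppm, 4 weeks), 6 and 23 (KO and TG minus WT change at 1 week), 6 and 12 (at 4 weeks) and 0 (difference between times), and all 36 genes of WT at 120 ppm and 1 week were among the 1161. The median over probe sets gave 4 and 0, and the trend with robust hyperparameters 5 and 0, for TG at 120 ppm after 1 and 4 weeks.

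Replicate numbers were taken not to pair animals. In 0 of 12 comparisons did every correlation of same-number animals exceed 0.1 (range -0.61 to 0.47). Weak pairing could also fail this rule and is not excluded. With the replicate block, counts were 80 for TG against WT and 10 for TG at 120 ppm and 4 weeks.

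Array weights gave 143, 208 and 54 (KO against WT, TG against WT, TG against KO), 2446 and 2 (WT and KO, 40 ppm, 1 week), 87 and 209 (WT, 40 and 120 ppm, 4 weeks), 10 and 15 (KO, 4 weeks), 73 and 106 (TG, 4 weeks), 407 (TG minus WT change at 1 week), 6 and 33 (KO and TG minus WT change at 4 weeks), 1 (120 against 40 ppm, 4 weeks) and 292 (between times). Without the 4 arrays of low weight, counts were 87 (TG against WT), 1385 and 2800 (WT, 40 and 120 ppm, 1 week), 2 (KO, 40 ppm, 1 week), 41 and 118 (WT, 4 weeks), 4 and 4 (KO and TG, 40 ppm, 4 weeks), 693 (KO minus WT change at 1 week) and 367 (between times), and 1058 of the 1161 genes of WT at 120 ppm and 1 week were among the 2800. With the poly-A covariate they were 75, 101 and 43 (strains in the order above), 1465 and 3123 (WT, 1 week), 3 (TG, 120 ppm, 1 week), 57 and 116 (WT, 4 weeks), 22 (TG, 40 ppm, 4 weeks), 1515 and 1249 (KO and TG minus WT change at 1 week) and 247 (between times).

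With each animal left out in turn, counts ran from 33 to 98 (TG against WT), 472 to 895 and 628 to 1844 (WT, 40 and 120 ppm, 1 week), 12 to 26 and 47 to 69 (WT, 4 weeks), 0 to 1 and 0 to 7 (KO, 1 week), 0 to 8 and 1 to 6 (KO, 4 weeks), 0 to 1 and 2 to 13 (TG, 1 week), and 0 to 1 and 0 to 2 (TG, 4 weeks). They ran from 158 to 828, 300 to 1858 and 0 to 1 (KO minus WT, TG minus WT and TG minus KO change, 1 week), 2 to 6 (TG minus WT, 4 weeks), 0 to 6 and 0 to 1 (120 against 40 ppm, 1 and 4 weeks) and 90 to 296 (between times). Cyp2f2 stayed between -1.43 and -1.37 for KO and between -1.41 and -1.35 for TG against WT.

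The p53 list median in WT lungs at 120 ppm and 1 week turned to 0.0295 with quantile normalization applied again and to 0.0512 both without the 4 arrays and without WT animal 3 at 120 ppm alone. Nr4a3 turned with the median of its probe sets, to 0.0935 (WT, 120 ppm, 1 week), 0.0988 (WT, 40 ppm, 4 weeks) and -0.242 (TG minus WT change at 1 week). The substrain list median between TG and KO turned to -0.0101 without the 4 arrays, -0.00357 without TG control animal 5 at 1 week and -0.000662 without KO control animal 3 at 4 weeks, and the immediate early list in WT at 40 ppm and 1 week to 0.0349 without control animal 1. With each animal left out in turn, the lowest immediate early median was -0.291, the lowest p53 median -0.110 and the highest substrain median 0.04815. The cause was not tested.

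For the named genes, the direction and the side of the threshold were the same for 205 values with quantile normalization applied again (9 weaker, 1 stronger), 190 with the median over probe sets (22 weaker, 3 reversed), 131 with only the arrays compared (84 weaker), 214 with the replicate block (1 weaker), 141 with dim genes left out (6 weaker), 208 with the trend (7 weaker) and 197 with array weights (8 weaker, 10 stronger). They were the same for 196 without the 4 arrays (11 weaker, 8 stronger), 207 with the poly-A covariate (5 weaker, 3 stronger) and 2902 with an animal left out (336 weaker, 22 stronger). For the lists, 84 values were labelled weaker with an estimated correlation (16 the same) and 72 with fry (28 the same). These labels also cover lists that passed in neither test, so they do not count lost calls. An example is the cell cycle list of the TG minus WT change at 4 weeks. Its camera adjusted p was 0.085 at the preset correlation and 0.80 at an estimated one.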

Other observations

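No test in this part goes beyond the lists fixed before the data were examined.

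The list of 12 heat shock genes had negative medians in most exposure comparisons without passing with an estimated correlation. In WT lungs the medians were -0.49 and -0.51 at 40 and 120 ppm after 1 week and -0.42 and -0.50 after 4 weeks, in KO lungs -0.21 (list adjusted p = 0.59), -0.54 (0.088), -0.15 (0.88) and -0.22, and in TG lungs 0.11 (0.98), -0.30, -0.38 and -0.48 (0.054). In WT lungs at 120 ppm, Hspa1b fell at 1 week (-1.60, SE 0.51, adjusted p = 0.038, but up to 0.20 with 6 of 10 animals left out in turn) and Hspb1 at 4 weeks (-0.79, SE 0.20, adjusted p = 0.035). The skeletal muscle list had a median of 0.81 in TG lungs at 40 ppm and 4 weeks, with 11 genes higher when adjusted over the list alone (adjusted p = 0.17 with an estimated correlation).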
